A study of Homo sapiens with 14 samples.

How the data were processed

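EZH2 CUT&RUN was done in HEK293T cells, with 3 libraries in each of 4 groups made of the aptamer (individual or dual-specificity) and the medium (without Wnt3A or with 50% conditioned medium). Per the labels, the medium was changed 20 h and the cells were harvested 24 h after transfection. Each reaction had 500 ng of EZH2 antibody and 0.5 ng of E. coli DNA as a spike-in. Of the 14 samples in the labels, the IgG and the input sample were not analysed here. Whether they served as the background in peak calling is unknown, and a peak here means only a peak of the authors' lists.

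Per the submitters' processing notes, the tools were Trim Galore, Bowtie2, SAMtools, bedtools, SEACR, DiffBind and ChIPseeker, with no versions, on the human build GRCh38.p13 and the E. coli build ASM584v2. The authors called peaks for each library separately with the stringent setting of SEACR, and the deposited signal of a peak is its total coverage and its highest coverage. The deposited signal had been multiplied by 1 factor per library, whose origin the files do not state, since heights were whole multiples of 1 step within 0.02 of a step at 99.99% to 100% of the peaks of each library. Total signal was not tested for the same factor. That step was taken as the worth of 1 fragment. Read totals were not in the files, so the depth of a library is not known, and that step is at most an indirect guide to it. The authors' deposited tables of differential sites, 1 per medium, give log2 group values, a log2 fold, a p-value and an FDR for each site of 401 bp, with the annotation of the nearest gene. The group values and the fold are the authors' DiffBind output and have no replicates in the tables. The fold was smaller than the difference of the log2 group values (median 0.55 against 0.76 without Wnt3A in the authors' deposited tables), and the tables held only sites with an FDR under 0.05. The number of tested sites was inferred from the authors' p-value and FDR columns.

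Peaks that overlapped by at least 1 bp were merged over all libraries. Values per library (number of peaks, covered length, median width, median height, share at gene ends) were compared by two-sided exact permutation tests of the difference of means. Each single comparison had 20 arrangements and a smallest p of 0.1. Tests over both media permuted labels within each medium, with 400 arrangements and a smallest p of 0.005. Benjamini-Hochberg adjustment ran over the 7 comparisons of each measure. A region had a group-specific call when 3 of 3 libraries of 1 group and 0 of 3 of the other had a peak there. Signal changes were tested with limma 3.58.1 in R 4.3.3 on the log2 of the highest peak in a region, for the 5677 regions called in all 12 libraries, centred on the median of each library, with all 4 groups in the fit and an adjusted p under 0.05. The centring removes any change common to all regions, so the differences of single regions are relative to that change. Limma was tested on simulated data with the spread of the real regions.

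Before the data were examined, 11 gene lists were fixed: HOX cluster genes, developmental transcription factors, Wnt/β-catenin target genes, Wnt ligands, receptors and antagonists, cadherins and epithelial-mesenchymal transition genes, CDK inhibitors and tumour suppressors repressed by EZH2, neuronal genes, blood and immune lineage genes, kidney epithelial genes, ribosomal protein and glycolysis genes, and the PRC2, O-GlcNAc and β-catenin machinery. Tests, the rule for named genes and most alternatives were set at the same time. Lists were tested with camera at a preset correlation of 0.01, with Fisher's exact test for peaks at 19970 protein-coding genes, and with Fisher's exact test among the authors' sites against the 12234 genes with a region in at least 2 libraries. Adjustment ran over the lists. Genes were placed with a reference table of assembly GRCh38.p14, which gives no strand. The planned window around transcription start sites was therefore replaced by 3000 bp around either end of a gene. That window held 87.6% (without Wnt3A) and 86.3% (with Wnt3A) of the gene and site pairs that the authors' tables place at a promoter within 3 kb. Coordinates are those of the authors' files. For named sites of the authors' tables, the authors' own promoter annotation was used.

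The rule named, for each of the authors' tables, the 8 promoter sites of protein-coding genes with the lowest FDR in each direction and up to 12 members of the fixed lists. For each limma comparison it named the regions past the threshold or, as none passed, the 3 with the lowest p in each direction near a protein-coding gene, as values. It also named AXIN2, LEF1, SP5, NKD1, CCND1, MYC, EZH2, CTNNB1 and OGT wherever they had a region. Regions that passed only when adjusted over the list alone were named as well, which the rule did not ask for.

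Alternatives covered a stricter peak height, chromosomes 1 to 22 and X, another overlap, other normalizations and measures, no centring, an imputed floor, a filter on low values, limma's trend and robust options, a narrower window of 1000 bp, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were a common floor of total signal, the regions called in all libraries, summed signal, gene bodies, draws matched on signal and centring of the comparison with the authors' fold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.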

Results

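EZH2, the histone methyltransferase of Polycomb repressive complex 2, was mapped by CUT&RUN, in which an antibody-tethered nuclease releases the chromatin around a bound protein. The cells were HEK293T, a human embryonic kidney line, transfected with plasmids for RNA aptamers. The control cells carried individual aptamers, and the other cells carried a dual-specificity aptamer that, per the labels, raises O-GlcNAc, a sugar modification, on β-catenin, the transcriptional effector of Wnt signalling. Each aptamer was studied in medium without Wnt3A and in medium with 50% Wnt3A-conditioned medium, with 3 libraries in each of the 4 groups. The design addresses whether EZH2 binding differs with the aptamer, and whether that difference depends on Wnt. The labels do not say whether the replicates were separate cultures, so p-values from comparisons of libraries measure only the spread between these libraries. The Fisher exact tests and the matched draws of genes compare numbers of genes and do not measure that spread. All peak signals are the authors' values. The deposited peak lists held between 7743 and 20764 peaks per library. They gave no read totals, but 1 step of the signal, taken as 1 fragment, was worth 0.746 to 2.23 units, and the median peak of a library reached a height of 7 to 25 fragments. Peaks of all libraries merged into 28441 regions, of which 5677 (20.0%) were called in all 12 libraries and 11748 (41.3%) in a single library.

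EZH2 peaks were found more often than at other genes at the ends of genes for developmental transcription factors, Wnt target genes and neuronal genes. Of these, genes for developmental transcription factors and neuronal genes are known as Polycomb targets outside the tissues that use them. With individual aptamers and no Wnt3A, 103 of 135 developmental transcription factor genes (76.3%) had a peak within 3000 bp of a gene end in at least 2 of 3 libraries, against 48.5% of other protein-coding genes (odds ratio 3.42, Fisher exact test, adjusted p = 6.3e-10). In the same group the share was 85.0% for Wnt/β-catenin target genes (adjusted p = 1.87e-05), 73.2% for neuronal genes (0.00451), 77.3% for CDK inhibitors and tumour suppressors repressed by EZH2 (0.0159) and 68.2% for Wnt ligands, receptors and antagonists (0.0159). These 5 lists were also above the other genes in each of the remaining 3 groups, with adjusted p of at most 0.0452. The CDK inhibitor and tumour suppressor list lost its call in a window of 1000 bp in 3 groups (Fisher exact adjusted p = 0.0708, 0.118 and 0.114), and at a common floor of total signal in 2 (0.106 and 0.161). Genes of the blood and immune lineage carried peaks less often than other genes in every group, at 18.8% (adjusted p = 0.00221) with individual aptamers and no Wnt3A and 9.38% (0.000735) with the dual aptamer and Wnt3A, though at the common floor not with individual aptamers and Wnt3A (0.0586). Kidney epithelial genes were also below other genes, at 19.2% (adjusted p = 0.00593) with individual aptamers and no Wnt3A, but not with the dual aptamer and Wnt3A (adjusted p = 0.0674). The kidney list lost every call at the common floor (adjusted p = 0.0712, 0.0722 and 0.161 in the groups that had passed), 1 when 3 of 3 libraries were required (0.0698) and 1 over gene bodies (0.191), and in a window of 1000 bp it passed with the dual aptamer and Wnt3A (0.033). Genes of the PRC2, O-GlcNAc and β-catenin machinery passed without Wnt3A (72.4%, adjusted p = 0.0197, with individual aptamers and 79.3%, 0.0259, with the dual aptamer) but not with it (adjusted p = 0.131 and 0.0767), a split that depended on the setting. Without Wnt3A this list failed when 3 of 3 libraries were required (adjusted p = 0.117 and 0.0836), and with Wnt3A it passed over gene bodies (0.0127 and 0.00339). HOX cluster genes (59.0%, adjusted p = 0.25, with individual aptamers and no Wnt3A), cadherin and epithelial-mesenchymal transition genes (56.7%, 0.512) and ribosomal protein and glycolysis genes (46.8%, 0.884) did not differ from other genes by this test in any group. Within the regions called in all 12 libraries, the median peak height was 29.5 for developmental transcription factors, 34.3 for neuronal genes and 32.9 for Wnt ligands, receptors and antagonists. The median of all these regions was 24.2. Among 10000 random lists of the same size, the list medians lay at percentiles 99.97, 99.8 and 99.51. The medians of Wnt/β-catenin target genes (24.8, percentile 59.23) and of CDK inhibitors and tumour suppressors (19.1, percentile 4.67) were not high in that way. The random lists were drawn from all these regions, near a gene or not, while each list gene was given its strongest region. A high percentile therefore does not show more signal than at the ends of other genes. Genes are not independent replicates, and whether the lists differed between groups was not tested.

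**Figure D1:**
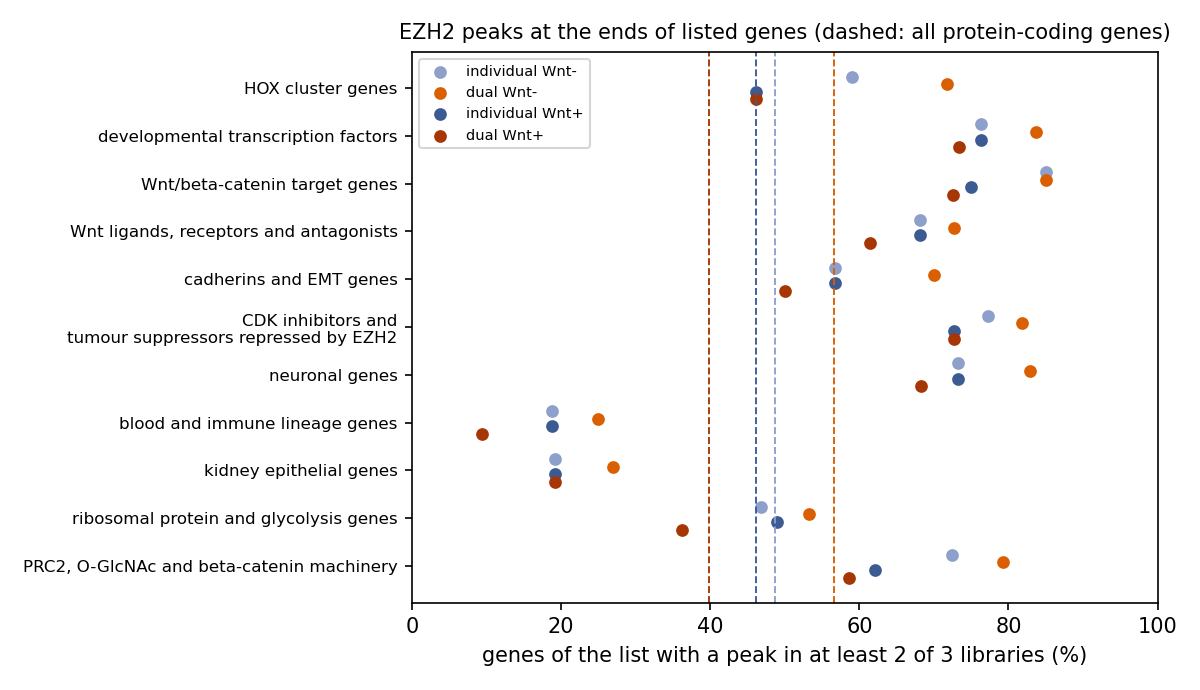
Share of the genes of each list (x axis, percent) with an EZH2 peak within 3000 bp of a gene end in at least 2 of 3 libraries, with 1 point per group and a dashed line for all protein-coding genes of that group. Developmental transcription factors lay at 73.3% to 83.7% and blood and immune lineage genes at 9.38% to 25.0%.

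Without Wnt3A, every site in the authors' deposited table of differential EZH2 binding was higher with the dual aptamer than with individual aptamers: 923 sites higher and 0 lower, at a median of 1.47-fold. The largest fold in the authors' deposited table, 86.7 (FDR 4.7e-31), was at RN7SL181P, a site treated apart below. The promoter of FBXL7, an F-box protein gene, had the lowest FDR among protein-coding genes in the authors' deposited table (chromosome 5, 15499907 to 15500307, GRCh38.p13), at 1.46-fold with an FDR of 4.6e-09. It was followed there, in the authors' deposited table, by CTNND2, which encodes the neuronal δ-catenin (1.40-fold, FDR 5.85e-08), the progesterone receptor gene PGR (1.54-fold, 5.48e-07), the neuronal migration gene ASTN2 (1.50-fold, 7.67e-07), C11orf96 (1.54-fold), the teneurin gene TENM4 (1.45-fold), RELN, which guides the positioning of neurons (1.49-fold), and VSTM2A (1.54-fold). Of the fixed lists, neuronal genes were the only one over-represented among these sites in the authors' deposited table, with 11 of 36 genes (30.6%, against 7.02% of other genes with an EZH2 region, Fisher exact adjusted p = 0.000271). The 11 genes included SYP (1.596-fold in the authors' deposited table), which encodes a synaptic vesicle protein, and the glutamate receptor genes GRIN1 and GRIN2A. When genes were drawn with matched EZH2 signal, 5.77 neuronal genes were expected by chance and the adjusted p was 0.244, so the call was not kept. Among developmental transcription factors, the authors' deposited table listed NEUROD2 (1.46-fold), NEUROG3 (1.64-fold), POU3F1 (1.40-fold), EBF3 (1.34-fold) and ONECUT2 (1.42-fold), and the list as a whole had 13 of 119 genes (adjusted p = 0.289). Further list members in the authors' deposited table were the Wnt ligand gene WNT11 (1.68-fold), the Wnt potentiator RSPO2 (1.56-fold), the cadherin gene CDH4 (1.43-fold), the B cell factor PAX5 (1.42-fold) and KLF4, a transcription factor used in reprogramming (1.74-fold). The other lists had between 0 and 5 genes with a site, with adjusted p of at least 0.289. Of the 923 sites, 820 (88.8%) were placed at a promoter of up to 1 kb in the authors' deposited table, and the p and FDR columns implied that 7618 sites had been tested.

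At single regions without Wnt3A, differences between aptamers were tested relative to the median of the 5677 shared regions, and none passed. The lowest p-values belonged to regions at CLSTN1, a calsyntenin gene, where the peak height was 26.5 ± 1.49 (SD, n = 3) with the dual aptamer and 10.97 ± 1.48 (SD, n = 3) with individual aptamers, and at RNASEH1, which encodes an RNA-DNA hybrid nuclease, where it was 15.5 ± 6.83 and 27.5 ± 2.57. Their log2 differences were 1.04 (SE 0.22) and -1.17 (SE 0.25), each with a limma adjusted p of 0.34. Regions at CCNP (0.90) and EEFSEC (0.92), which also lie near other genes, had log2 values above 0, and the region at LBR, the lamin B receptor gene, had -1.06. The region at EZH2 itself (chromosome 7, 148883279 to 148885415) was at 14.96 ± 1.62 (SD, n = 3) with the dual aptamer and 23.3 ± 4.23 (SD, n = 3) with individual aptamers, a log2 difference of -0.87 (SE 0.22, limma adjusted p = 0.421, and 0.00741 adjusted over the list alone). KLF4 (chromosome 9, 107488207 to 107490778) had a log2 difference of 0.95 (SE 0.23, limma adjusted p = 0.421, and 0.00434 adjusted over the list alone). Adjusted over the list alone, 1 region of the CDK inhibitor and tumour suppressor list and 1 of the machinery list passed, and 0 of the other lists. The Wnt targets AXIN2 (-0.22), SP5 (0.06), NKD1 (0.00), CCND1 (0.08) and MYC (-0.21) had log2 differences that did not pass (limma adjusted p between 0.941 and 1.00), and LEF1, CTNNB1 and OGT had no region called in all libraries. Limma with median centring called 0 regions, with 329 at an unadjusted p under 0.05, and recovered 62.0% of simulated log2 changes of 1 but 6.00% of changes of 0.5. Without centring it called 7 regions, all higher, and with uncalled values set to the lowest height of a library it called 148, of which 142 were higher. In every comparison that last setting tested 11468 regions, called in all 3 libraries of at least 1 group. A region that entered through 1 group alone is high there by that choice, so the counts of this setting do not support a direction. In calls alone, 400 regions had a peak in all 3 dual-aptamer libraries and in 0 of 3 individual-aptamer libraries, and 8 regions the reverse, in lists whose lowest signals were unequal. These became 183 and 14 at a common floor, and 195 and 77 when peaks had to cover at least 50% of the region. None of the 11 lists passed the camera test in this comparison (lowest adjusted p = 0.629, for the machinery list, and 0.786 with an estimated correlation).

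With Wnt3A, the authors' deposited table again listed only sites that were higher with the dual aptamer, 3473 higher and 0 lower, at a median of 1.56-fold. RN7SL181P again had the largest fold in the authors' deposited table, 116 (FDR 9.83e-31). PRDM8, a gene of the PR-domain family of chromatin regulators, had the lowest FDR among protein-coding genes in the authors' deposited table (chromosome 4, 80197904 to 80198304), at 1.82-fold with an FDR of 8.79e-08. Next in the authors' deposited table were TMEM132E (1.55-fold, FDR 3.56e-07), PGR (1.54-fold, 3.96e-07), the homeobox gene GSX1 (1.53-fold, 1.99e-06), NELL1 (1.48-fold), the adhesion receptor gene ADGRB3 (1.46-fold), FBXL7 (1.41-fold) and the neurite outgrowth gene NEXMIF (1.53-fold). Wnt target genes were listed for 15 of 35 genes (42.9%, against 25.95% of other genes) in the authors' deposited table, a share that did not pass after adjustment (Fisher exact p = 0.032, adjusted p = 0.136). They included the cell cycle gene CCND1 (1.50-fold), the transcription factor gene SP5 (1.54-fold) and AXIN2, a feedback inhibitor of the pathway (1.38-fold), with FDR between 0.0213 and 0.0452 in the authors' deposited table. Wnt ligands, receptors and antagonists had 15 of 33 genes (adjusted p = 0.136), among them the receptor gene FZD8 (1.54-fold) and the Wnt potentiator RSPO3 (1.73-fold), in the authors' deposited table. Neuronal genes had 15 of 36 (adjusted p = 0.136), with SYP (1.77-fold), the synaptic adhesion gene NRXN2 (1.65-fold) and the splicing factor gene RBFOX3 (1.59-fold) in the authors' deposited table. Developmental transcription factors had 40 of 119 (adjusted p = 0.163), with EBF3 (1.52-fold), POU3F2 (1.57-fold) and ONECUT2 (1.59-fold) in the authors' deposited table. The cadherin gene CDH6 (1.48-fold), CTNND2 (1.52-fold, at another promoter than without Wnt3A) and PAX5 (1.55-fold) were the other list members with the lowest FDR in the authors' deposited table. The remaining lists had 2 to 6 genes with a site and adjusted p of at least 0.23. Of the 3473 sites, 3017 (86.9%) were placed at a promoter of up to 1 kb in the authors' deposited table, and 14407 tested sites were implied.

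At single shared regions with Wnt3A, the lowest p-values for the aptamer in each direction belonged to CPEB4, a translational regulator, with 23.3 ± 1.69 (SD, n = 3) with the dual aptamer and 10.0 ± 1.98 (SD, n = 3) with individual aptamers, and to MYL12B, a myosin light chain gene, with 10.9 ± 1.43 and 15.7 ± 4.23. Their log2 differences relative to all shared regions were 0.91 (SE 0.27) and -0.83 (SE 0.22), with a limma adjusted p of 0.998. GON7 (0.77), RHOU (0.79), PHACTR2 (-1.08) and KYAT3 (-0.69) had similar sizes and the same adjusted p. AXIN2 (0.03), SP5 (0.42), NKD1 (0.08), CCND1 (0.12), MYC (-0.21) and EZH2 (0.12) did not pass. The tight junction gene OCLN had a log2 difference of -0.84 (SE 0.25, limma adjusted p = 0.998, and 0.0375 adjusted over the list alone), and it was the only region of a fixed list that passed in that way. Limma called 0 regions, with 202 at an unadjusted p under 0.05, and recovered 56.0% of simulated log2 changes of 1. With uncalled values set to the lowest height it called 23, of which 2 were higher and 21 lower. No list passed camera (lowest adjusted p = 0.881, and 0.885 with an estimated correlation). In calls alone, 14 regions had a peak in all 3 dual-aptamer libraries and 0 of 3 individual-aptamer libraries, and 168 the reverse. That direction turned to 231 against 2 when all libraries were held to the same lowest total signal of a peak. Such a fixed cut favours the group with the higher signal, so the turn is no separate evidence of more binding.

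Over both media, the median EZH2 peak height over the 5677 shared regions was higher in all 6 libraries with the dual aptamer than in any of the 6 libraries with individual aptamers. The median peak height over these regions was 27.3 ± 0.555 (SD, n = 3) against 23.1 ± 1.39 (SD, n = 3) without Wnt3A, and 27.4 ± 2.22 (SD, n = 3) against 21.9 ± 0.913 (SD, n = 3) with it. This was not so for total signal, where a dual-aptamer library with Wnt3A (10356) lay below an individual-aptamer library without it (10420), at 1.23-fold over both media (log2 0.30, exact permutation p = 0.005). For height the difference was 1.22-fold over both media (log2 0.28, two-sided exact permutation p = 0.005, the smallest that 400 arrangements within media can give), a measure chosen after the data were examined. It was 0.24 without and 0.32 with Wnt3A on the log2 scale. An exact test of their difference gave p = 0.705, but it permuted aptamer labels within each medium and so presumed no aptamer difference. That p therefore cannot tell whether the shift depended on Wnt3A. Without centring, 84.7% of the shared regions without Wnt3A and 90.4% with it lay above 0. Regions were shared only if every library called them, and the lowest total signal of a listed peak was unequal. In dual-aptamer replicates 2 and 3 with Wnt3A it was 5804 and 5806, against 3179 in replicate 1. This could raise their medians, which were 28.4 and 29.0, against 24.9. In dual-aptamer replicates 2 and 3 without Wnt3A it was only 2387, and their medians were 26.8 and 27.9. The authors' sites were chosen from the same libraries for being higher with the dual aptamer, so their direction in the library lists (100% of 832 sites higher without Wnt3A and 99.4% of 2502 with it) is no separate evidence. After centring, 86.9% and 73.2% of these sites were higher, against 45.5% and 33.9% of other regions. Without centring, the shares of other regions were 81.3% and 84.0%. Across sites, which are not independent replicates and come from the same libraries, Spearman's rho between the fold in the authors' deposited table and the difference in peak height was 0.64 without and 0.62 with Wnt3A.

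**Figure D2:**
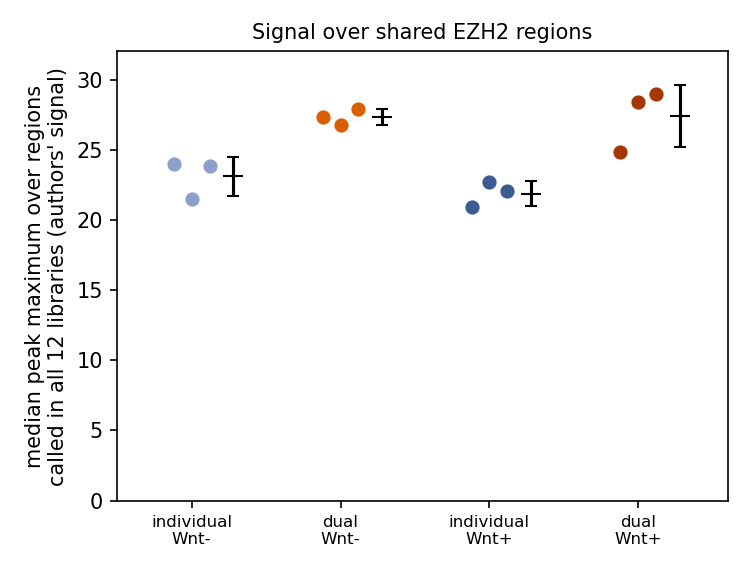
Median EZH2 peak height over the regions called in all 12 libraries (y axis, the authors' signal units), with 1 point per library and the mean ± SD of each group. The 6 dual-aptamer libraries lay between 24.9 and 29.0 and the 6 individual-aptamer libraries between 20.9 and 24.0.

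**Figure D3:**
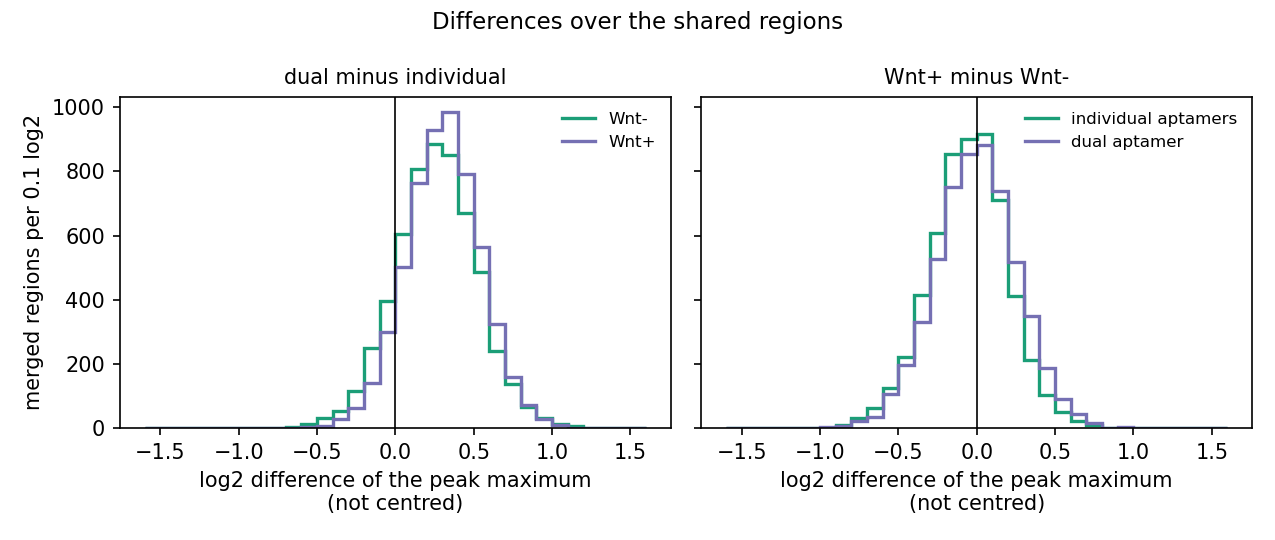
Number of shared regions (y axis) by log2 difference in peak height (x axis, not centred), for the dual against individual aptamers in each medium and for Wnt3A against none with each aptamer. The median was 0.26 and 0.31 for the aptamer, and -0.04 and 0.00 for Wnt3A.

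The aptamer sites of both media overlapped. The authors' deposited tables shared 533 sites, which was 57.7% of those without Wnt3A and 15.3% of those with it. They included the promoters of PGR and FBXL7, which were among the 8 sites with the lowest FDR in each of the authors' deposited tables. Counted in merged regions, 535 held a site of both tables, against a mean of 191 over 1000 circular shifts along the regions (highest 234) and a mean of 472 over draws matched on EZH2 signal (highest 507). The tables compare libraries of different media.

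The number of EZH2 peaks and their share at gene ends spread most among the dual-aptamer libraries. Without Wnt3A there were 18261 ± 2831 (SD, n = 3) peaks with the dual aptamer and 11821 ± 868 (SD, n = 3) with individual aptamers. With Wnt3A there were 9430 ± 2009 (SD, n = 3) and 10898 ± 301 (SD, n = 3). Over both media the dual aptamer had 2486 more peaks (exact permutation p = 0.165, adjusted p = 0.231), and the single comparisons gave exact p = 0.1, the smallest possible, without Wnt3A (adjusted p = 0.175) and 0.4 with it (adjusted p = 0.4). For Wnt3A the exact p was 0.3 with individual aptamers (difference -923, adjusted p = 0.35) and 0.1 with the dual aptamer (-8831, adjusted p = 0.175). The lowest total signal of a listed peak was 2387 in dual-aptamer replicates 2 and 3 without Wnt3A, 5804 and 5806 in replicates 2 and 3 with it, and 3178 to 3179 in the other 8 libraries. At a common floor of 5806, the dual-aptamer libraries had 1466 more peaks without Wnt3A and 1803 more with it, and over both media 1634.5 more (exact permutation p = 0.005). A fixed cut admits more peaks where all signal is higher, and total signal over the shared regions was 1.23-fold higher with the dual aptamer. The peak numbers at the floor are therefore no evidence separate from that shift, which a scale factor could also give. Peaks covered 18.0 ± 2.38 Mb (SD, n = 3) with the dual aptamer and 14.7 ± 3.72 Mb (SD, n = 3) with individual aptamers without Wnt3A, and 12.9 ± 1.87 Mb and 13.8 ± 1.64 Mb with it (over both media 1.25 Mb, exact p = 0.455, adjusted p = 0.637). The median peak width was 864 ± 237, 1082 ± 196, 1225 ± 265 and 1108 ± 122 bp in the same order of groups (-50.4 bp, exact p = 0.685, adjusted p = 0.799). Median peak height over all peaks of a library was 15.7 ± 0.877, 16.3 ± 1.35, 22.2 ± 3.17 and 16.1 ± 0.459 (2.77, exact p = 0.105, adjusted p = 0.147). The share of peaks at gene ends was 59.3% ± 6.47, 72.9% ± 1.99, 75.8% ± 3.67 and 74.5% ± 2.11 (-6.15 percentage points, exact p = 0.115, adjusted p = 0.161). Of the 11748 regions called in a single library, 9303 came from dual-aptamer replicates 2 and 3 without Wnt3A. In these libraries 1 fragment was worth 2.23 and 1.86 units, the most of all libraries, and the median peak reached only 7 and 8 fragments. Their median widths (687 and 771.5 bp) and shares at gene ends (56.7% and 54.5%) were the lowest of all libraries. The group values without Wnt3A therefore rest largely on 2 libraries with few fragments per peak.

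**Figure D4:**
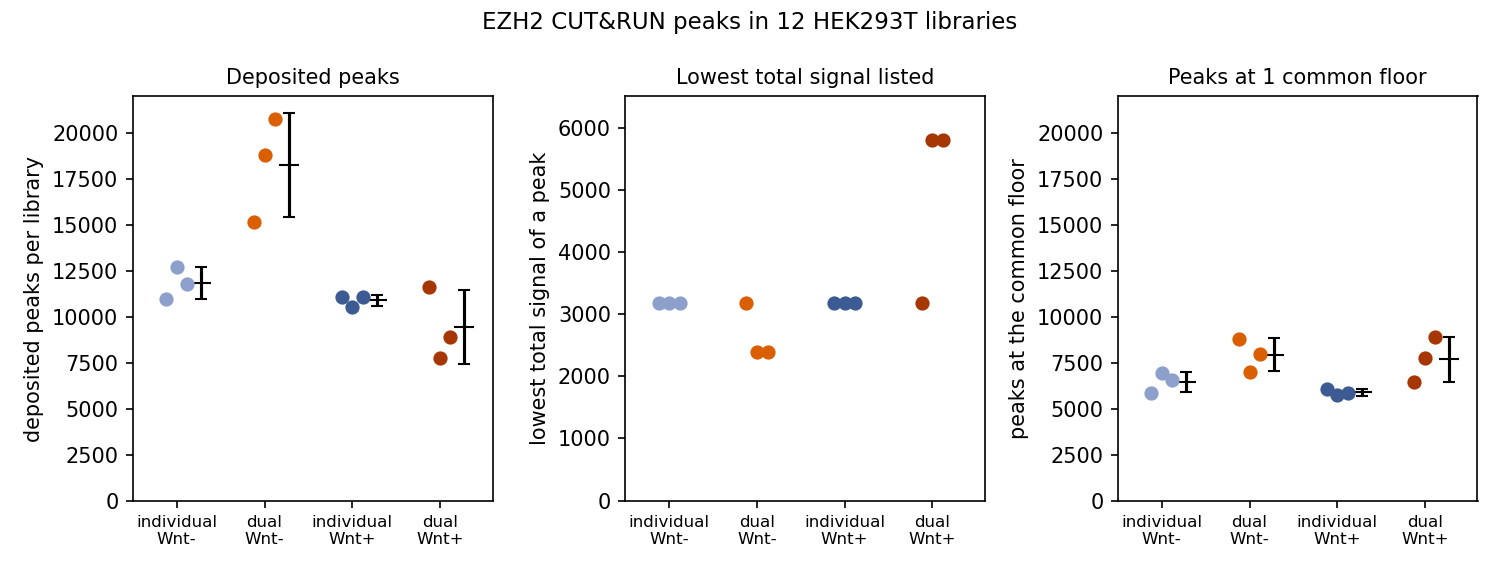
Deposited EZH2 peaks per library, the lowest total signal listed in each library, and the number of peaks at or above a common floor of 5806 (y axes), with 1 point per library and the mean ± SD of each group for the peak numbers. The number of deposited peaks ran from 7743 to 20764 and the number at the common floor from 5733 to 8894.

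For Wnt3A in cells with individual aptamers, regions at the potassium channel gene KCNH1, with 31.6 ± 7.39 (SD, n = 3) with Wnt3A and 18.5 ± 4.82 (SD, n = 3) without, and at TLE3, a Groucho-family corepressor that acts with TCF factors, with 10.1 ± 1.54 and 18.6 ± 3.69, were among those with the lowest p-values. Their log2 differences were 0.86 (SE 0.22) and -0.80 (SE 0.21), each with a limma adjusted p of 0.918. The syndecan gene SDC1 (0.90), AP1AR (0.80), ZNF195 (-0.92) and NRBP2 (-0.92) had the same adjusted p. The Wnt targets AXIN2 (0.19), SP5 (0.34), NKD1 (0.24), CCND1 (-0.04) and MYC (-0.40) did not pass, nor did EZH2 (-0.66, SE 0.22). Limma called 0 regions, with 287 at an unadjusted p under 0.05, and 0 regions adjusted over the list alone. With uncalled values set to the lowest height it called 15, of which 1 was higher and 14 lower. No list passed camera, where the lowest adjusted p was 0.214, for the PRC2, O-GlcNAc and β-catenin machinery (0.446 with an estimated correlation). In calls alone, 29 regions had a peak in all 3 libraries with Wnt3A and 0 of 3 without, and 117 the reverse.

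For Wnt3A in cells with the dual aptamer, regions at PRR16, with 36.0 ± 5.32 (SD, n = 3) with Wnt3A and 18.4 ± 1.74 (SD, n = 3) without, and at PROK2, a prokineticin gene, with 17.5 ± 2.05 and 34.04 ± 9.16, had log2 differences of 0.96 (SE 0.22) and -0.94 (SE 0.22), each with a limma adjusted p of 0.591. The glutamate receptor gene GRIN2C (0.93), FAM117A (0.82) and FAM193A (-1.03) also had limma adjusted p of at least 0.591. Of the fixed genes, SP5 had a log2 difference of 0.69 (SE 0.23, limma adjusted p = 0.756) and AXIN2 of 0.44 (SE 0.21, limma adjusted p = 0.819), followed by NKD1 (0.32), EZH2 (0.34), CCND1 (0.01) and MYC (-0.40). In the HOX list, whose genes set body position, 4 of 6 regions passed when adjusted over the list alone and 0 over all regions. These included HOXD8 (0.77, limma p over the list alone 0.0123), which was higher with Wnt3A, and HOXB9 (-0.68, 0.0123) and HOXA13 (-0.63, 0.0371), which were lower. The list as a whole did not pass camera (adjusted p = 0.949), and neither did any other (lowest adjusted p = 0.949, and 0.956 with an estimated correlation). Limma called 0 regions, with 338 at an unadjusted p under 0.05, and recovered 78.0% of simulated log2 changes of 1. With uncalled values set to the lowest height it called 95, all lower, in lists whose lowest signals were unequal and among regions chosen for calls in all 3 libraries of some group. In calls alone, 1 region had a peak in all 3 libraries with Wnt3A and 0 of 3 without, and 994 the reverse, which at the common floor became 37 and 62.

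Over both aptamers, the number of EZH2 peaks per library differed by -4877 with Wnt3A (exact permutation p = 0.015, adjusted p = 0.07 over the 7 comparisons of that measure). At the common floor that difference was -409 (exact p = 0.365). Signal over the shared regions differed by -0.04 on the log2 scale (exact p = 0.425). The share of peaks at gene ends was 9.07 percentage points higher with Wnt3A (exact p = 0.025, adjusted p = 0.14), and 0.578 at the common floor (exact p = 0.375). Covered length differed by -3.03 Mb (exact p = 0.095, adjusted p = 0.35), median width by 193 bp (exact p = 0.17, adjusted p = 0.467) and median height by 3.20 (exact p = 0.065, adjusted p = 0.147).

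Whether the aptamer difference itself depended on Wnt3A was tested at each shared region. MYL12B (log2 -1.39, SE 0.32) and CCNP (-1.34, SE 0.30) had the lowest p-values, with a limma adjusted p of 0.554, followed by PHACTR2 (-1.76), C19orf38 (1.21), FBXO22 (1.12) and GON7 (1.18). EZH2 had 1.00 (SE 0.32, limma adjusted p = 0.897), and AXIN2 (0.25), SP5 (0.35), NKD1 (0.08), CCND1 (0.04) and MYC (0.00) did not pass. Limma called 0 regions, with 269 at an unadjusted p under 0.05. Among the values per library, the difference of the aptamer differences was -7908 peaks (exact p = 0.02, adjusted p = 0.07), 6.66 for median height (0.03, 0.147) and 14.9 percentage points for the share at gene ends (0.04, 0.14). For covered length it was -4.27 Mb (exact p = 0.175, adjusted p = 0.35) and for median width 336 bp (0.19, 0.467). These exact tests permuted aptamer labels within each medium, so a large p does not show that the aptamer differences were equal.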

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

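The explanations in this part, and what each would predict, were written after the results were seen. The limma region tests, and the comparison of group-specific calls in the deposited peaks with other splits, had been planned. The aptamer difference with Wnt3A minus that without it was set apart for 3 measures, because an exact test of the difference between the media had p under 0.05: -7908 for peaks per library, 6.66 for median peak height and 14.9 percentage points for the share of peaks at gene ends. None of the 3 passed after adjustment.

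The number of EZH2 peaks was higher with the dual aptamer without Wnt3A and lower with it, and the lowest total signal of a listed peak was unequal in the same libraries. At 1 common floor the difference with Wnt3A became 1803, and 1200.5 to 2432 with a library left out. The opposite directions could therefore come from unequal peak-calling thresholds, and the 3 values set apart rest on the same lists. A biological loss of weak peaks with Wnt3A would not by itself predict a lowest signal of 5804 and 5806 in only 2 libraries. The common floor sets aside all peaks below it, so it cannot show whether such a loss also occurred.

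Median EZH2 peak height over the shared regions was higher in all 6 dual-aptamer libraries, and with Wnt3A the unequal lowest signals could contribute. Whether depth could be the cause stays open: adjusting for the worth of 1 fragment left a log2 difference of 0.279, close to the unadjusted 0.28, and 4 dual-aptamer libraries with a worth in the range of the individual ones had medians of 24.9 to 29.0 against at most 24.0, but how far that worth follows depth is unknown. The shift was of similar size from weak to strong regions (exact p = 0.64 for the strongest against the weakest 25% of regions), which is what the authors' scale factor would give and equally what a uniform effect of the aptamer would give. The RNU6-1 peak, which a factor alone would move as much, was 1.07-fold higher (exact p = 0.02), and the shift relative to it was 1.14-fold (exact p = 0.025), but if it comes from plasmid it also follows transfection. These files cannot separate the causes, and a change in scale might also underlie the absence of lower sites in the authors' deposited tables.

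Beside the U6 snRNA gene RNU6-1 a peak reached 46153 to 56714 in all 12 libraries, 112 to 169 times the next peak, and its summit differed by 27 bp between all individual-aptamer and all dual-aptamer libraries. The highest peak at the 4 other U6 genes was 20.2, so reads from a U6 promoter on the plasmids could explain it, though the labels do not name the promoter. On chromosome 9 (121203109 to 121203509) a site at RN7SL181P was called in 6 of 6 dual-aptamer and 0 of 6 individual-aptamer libraries. It had the largest fold in both of the authors' deposited tables, 86.7-fold (FDR 4.7e-31) without Wnt3A and 116-fold (FDR 9.83e-31) with it. The next largest folds there were 1.87 and 2.36. The widest peak at RN7SL181P was 327 bp, which does not resemble EZH2 gained over a chromatin region, while a narrow event or sequence shared with a plasmid remains possible. Without a genome or plasmid sequence neither could be tested.

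Group-specific calls were compared with the 10 ways to split 6 libraries, too few for a share under 0.05. With deposited peaks and then at the common floor, the real count and the highest other were 408 and 246, then 197 and 191, for the aptamer without Wnt3A, with 1 split as large each time. With Wnt3A they were 182 and 242 (3 splits), then 233 and 174 (1 split). For Wnt3A with individual aptamers they were 146 and 160 (3 splits), then 90 and 107 (5 splits), and with the dual aptamer 995 and 356 (1 split), then 99 and 186 (5 splits). Regions called by limma numbered 0 in each real split, against a highest other of 3, 0, 0 and 0, and for the interaction 0 against 1. A count of 0 makes all 10 splits, and all 100 drawn for the interaction, as large by construction, so these comparisons decide nothing.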

How the results depend on the processing

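Alternatives are counted against the values above. Of those for the chief results, 182 stayed the same, 40 moved, 7 became stronger and 4 reversed, and of the others 1167 stayed the same, 15 moved, 7 became stronger, 7 weaker and 23 reversed. The cause of these changes was not tested unless stated. Among the others, 929 alternatives belonged to 59 named region values, none of which had passed. Only 4 of the 929 passed, so for named regions staying the same means still not passing and is no sign of a stable effect. With a stricter peak height the aptamer difference over both media was 1925 peaks (exact p = 0.005), 2.14 Mb (0.01) and 1.33 in median height (0.03), which had not passed with all peaks. At a common floor it was 1634.5 peaks (exact p = 0.005), 2.10 in height (0.03) and -1.86 points in the share at gene ends (0.03). Both cuts are fixed in the authors' signal, so a common rise in signal with the dual aptamer would alone raise the peak numbers. Over the regions called in all libraries the height difference was 4.87 (exact p = 0.005). With Wnt3A the aptamer difference reversed to 1365 (stricter) and 1803 (floor) peaks, 2.20 and 2.46 Mb, -0.127 and -1.54 points at gene ends, 225 and 233 group-specific regions, and a width of -52.3 bp (floor). Without Wnt3A its median height reversed to 1.00 (stricter), 2.03 (floor) and 4.21 (shared regions). The value for median peak signal per library: Wnt over both aptamers reversed to -0.0336 with the common floor of total signal and to -0.575 over the regions called in all 12 libraries. For Wnt3A, height with individual aptamers to 0.779 (stricter), and covered length with the dual aptamer to 0.636 Mb (floor). Of 208 alternative values of single comparisons 21 had the other sign, 10 of them for the aptamer with Wnt3A. With 1 library left out, the aptamer difference over both media ran from 1860 to 3254 peaks, 0.397 to 2.24 Mb, -118 to 20.4 bp (2 without individual-aptamer replicate 2, no Wnt3A), 2.16 to 3.66 in height and -7.99 to -4.95 points at gene ends. Ranges that crossed 0 were, for the aptamer with Wnt3A, -1.86 to 0.0467 Mb, -2.67 to 259 bp and -0.228 to 3.35 points, and without it -1.25 to 0.105 in height. For Wnt3A with individual aptamers they were -2.59 to 1.10 Mb, -63.8 to 130.2 bp (-39.3 without Wnt3A-treated replicate 1) and -0.815 to 0.539 in height (0.106 without the same library). Group-specific regions at a floor were 197 without Wnt3A for the aptamer, and for Wnt3A 90 (also 90 stricter) with individual aptamers and 99 with the dual aptamer. The number of regions with a group-specific call: Wnt+ against Wnt-, dual aptamer was 200 with the stricter threshold on the peak maximum and 395 when peaks had to cover at least 50% of the region. With 1 library left out the rule needs only 2 libraries and the counts ran from 609 to 1083, 286 to 555, 297 to 433 and 1135 to 2087; every removal moved them more than 1.5-fold except individual-aptamer replicate 1 without Wnt3A in the first and dual-aptamer replicates 2 and 3 with Wnt3A in the last. Limma called 7 regions without centring (aptamer, no Wnt3A), and 148, 23, 15, 95 and 8 with uncalled values set to the lowest height, in the order of the report with the interaction last. With 1 library left out it called 0 to 1 region for the aptamer without Wnt3A and 0 elsewhere. An FDR under 0.01 left 174 and 900 sites of the authors' deposited tables. Matching on signal left 0 lists among them. After centring, 86.9% and 73.2% of the authors' sites were higher with the dual aptamer. Without centring, 99.0% were higher with Wnt3A when 4 of 6 libraries sufficed. Whether replicate numbers pair samples is unknown. Deviations of the regions from their group means had r of -0.040 to 0.011 between samples of the same number. Between samples of other numbers r was -0.027 to 0.031, so no shared pattern by number was seen. With the number as a replicate block in exact sign-flip tests, the aptamer difference of 2486 peaks had p = 0.281, the Wnt3A difference of -4877 had p = 0.0625 and the 9.07 points at gene ends had p = 0.125.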

Other observations

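Genes of the blood and immune lineage rarely carried EZH2, but the 3 shared regions at such genes had a median height of 61.9. This height was at percentile 98.96 of random lists drawn from all shared regions. At 6 regions of HOX genes the median height was 20.98 (percentile 21.95). With Wnt3A the authors' deposited table also placed sites at SOX9, BMP4, NOTUM and TBXT, and at APC, AXIN1 and TCF7L2 of the β-catenin machinery.

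At the EZH2 gene without Wnt3A, the mean peak height was 14.96 with the dual aptamer and 23.3 with individual aptamers (limma adjusted p = 0.421). The centred log2 difference ran from -1.04 to -0.78 with 1 library left out, which is no separate evidence, as the region was also named for its low p. With Wnt3A the mean height was 19.3 with the dual aptamer and 13.9 with individual aptamers (centred log2 difference 0.12). Individual aptamers without Wnt3A thus had the highest mean of the 4 groups. If the lower value with the dual aptamer holds, it might reflect feedback on EZH2 expression, which RNA and protein levels of EZH2 in the 4 groups would test. The difference without Wnt3A did not pass over all regions, so a targeted assay in new cultures would be needed.

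A uniform gain of EZH2 could follow from more EZH2 or from scale, and the exact p of 0.64 between strong and weak regions leaves both open. Counting E. coli reads per library, and H3K27me3 mapping with the same spike-in, would separate them. Mapping the reads to the plasmid sequences would test the sites at RNU6-1 and RN7SL181P.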
